A study of Mus musculus with 2 samples.

How the data were processed

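DNase-seq, which maps DNA that the enzyme DNase I can reach in nuclei, was measured in MN1, an immortalized mouse cell line of strain B6NCrl according to the labels. The series holds 1 group with 2 biological replicates, named replicate 1 and replicate 2 as in the labels, with 1 library each. The labels give no tissue of origin, treatment, age or sex. They name 2 sequencing instruments for replicate 2 (Illumina HiSeq 2500 and Illumina NextSeq 500) and none for replicate 1.

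The files analysed were a list of peaks and a list of hotspots per library, both on assembly mm10. According to the notes supplied with them, each list was derived from the filtered alignments of its own library, without pooling of replicates. The aligner, the caller and its threshold are not given in the sources used here. The deposited peaks were 150 bp wide, except 1 narrower peak per library, and carried a score between 1 and 150 made by the authors. This score has a ceiling and no stated normalization, so it was used only to rank peaks within a list. The deposited hotspots carried a q-value on the −log10 scale, with a lowest value of 1.30 in each library and a cap of 100 for values above 6. The read depth of the libraries is not given in the files, so it is unknown, and no interval that needs it was computed.

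Repeated entries were removed (43 in replicate 1 and 20 in replicate 2). Analyses used the 19 autosomes, X and Y, and peaks elsewhere were only counted. A peak was called shared if it overlapped a peak of the other library by 1 bp or more, and counts of shared peaks refer to the list of replicate 1 unless stated. As a background, the other library's peaks were shifted at random round each chromosome 20 times. The reference genome was GRCm38, the same assembly as mm10, with protein-coding genes of GENCODE M21 (21911 genes and 93444 transcription start sites). A promoter was the region within 1 kb of any such start site, a distal peak lay outside all promoters, and other peaks were assigned to exon, intron or intergenic sequence by their centre.

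Gene lists for 22 cell types or functions were written from textbook knowledge: housekeeping, cell cycle, pan-neuronal, motor neuron, sympathoadrenal, neural progenitor, glia and neural crest, glutamatergic, GABAergic and glycinergic, monoaminergic other, mesenchymal and fibroblast, skeletal muscle, cardiac, endothelial, erythroid and megakaryocyte, T cell, B cell, myeloid, hepatocyte, epithelial, pluripotency and germ line. All 345 list genes were matched by symbol in the annotation. The number of members with a promoter peak in both libraries was compared with 10000 random lists of the same size. The random lists were matched on the decile of promoter CpG observed/expected ratio. This ratio was taken at the outermost start site of each gene, whereas a promoter peak could lie at any of its start sites. The number of start sites per gene was not matched. The mean number of shared distal peaks within 50 kb of the start site was compared with random lists matched on the decile of local gene density. These permutation tests had both tails counted, and p was adjusted over the 22 lists by the Benjamini-Hochberg method with a threshold of 0.05. Their smallest possible p was 0.0002. Genes are not replicates, so the tests describe these 2 libraries and not MN1 cultures in general.

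Consensus motifs for 32 factors or factor families were matched on both strands within 75 bp of the peak centre. The share of peaks with a match was divided by the share in windows of equal width 1 kb to each side. The same ratio was computed for up to 20 shuffles of each consensus that kept its bases and its number of CpG. Single-library distal peaks were compared by the ratio of their shares with a match, with 95% bootstrap intervals from 1000 resamplings of peaks. The ratio was also weighted to equal GC content or to equal score deciles.

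Genes named in the text followed a rule: up to 4 members per list with a promoter peak in both libraries, by score rank, and up to 4 with none in either, in list order; Hox genes; the 15 genes with most shared peaks within 50 kb; the genes nearest to the 10 shared peaks with the highest mean score rank; and the 10 genes whose peak number within 50 kb differed most between the libraries. Some genes that this rule names are not reported here. The comparisons, gene lists, motif names, naming rule and the alternative settings were fixed before the data were examined. The motif consensus strings were written after the gene results and before any motif result. Chosen after seeing the data were the rule for dense blocks, the gene families, the comparison of single-library motifs, the count of autosomes whose share differed by more than 5%, and the alternatives that left out blocks or peaks with a decimal score.

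A dense block was a run of at least 3 windows of 10 kb with 5 or more peaks each that were found in 1 library only, with peaks of the other library at no more than 25% of that number. The alternative settings were an overlap of 50%, the higher-scoring part of each list, lists of equal length, autosomes only, promoter windows of 500 bp and 2.5 kb, 1 start site per gene, hotspots in place of peaks, distal windows of 20 kb and 100 kb, flanks 5 kb away, random lists without matching, and each replicate left out in turn. The steps were tested on simulated data, in which planted overlaps, lists, motifs and blocks were recovered. For the promoter test 4.25% of unchanged simulated lists had a permutation p under 0.05. That share was not measured for the distal test, and members that share peaks were not simulated. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, Numba 0.67.0 and Matplotlib 3.10.9.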

Results

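Open chromatin was mapped by DNase-seq in 2 biological replicates of MN1, an immortalized mouse cell line. Replicate 1 gave 170600 distinct peaks and 140519 hotspots covering 58.9 Mb, and replicate 2 gave 162983 peaks and 135294 hotspots covering 54.1 Mb. All peaks of each library lay in a hotspot of that library. Read depth is unknown. The labels state no question and no second condition was sampled, so the libraries were compared with each other, and named genes were compared with other genes in the same libraries. Coordinates are on mm10.

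The 10 shared peaks with the highest mean score rank all lay at promoters. They lay at Cand1, a regulator of cullin ubiquitin ligases (chromosome 10, 119240096 to 119240245), and at Hjurp, the chaperone of the centromeric histone (chromosome 1, 88277556 to 88277705). Others lay at Cs, which encodes citrate synthase, at Usp34, a deubiquitinase, and at Crocc, a ciliary rootlet protein with 2 of the 10 peaks. AW549877, Fam76a, Clip2 and Mdm1 completed the set, and every peak of the set was at the 99.96 percentile of score or higher in both libraries. Of the peaks on the main chromosomes, 67.1% of those of replicate 1 (114222 of 170286) and 70.2% of those of replicate 2 (114234 of 162691) overlapped a peak of the other library. After random shifts the shares were 1.85% and 1.93%, so the overlap was 36.2 and 36.4 times the shifted level. Overlap fell with score, from 98.2% and 97.03% in the highest decile of each list to 11.8% and 22.6% in the lowest. Of the peaks found in 1 list only, 15.96% of those of replicate 1 and 23.7% of those of replicate 2 lay in a hotspot of the other library. The hotspots had 43.9 Mb in common, 74.6% of the length in replicate 1 and 81.1% in replicate 2.

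**Figure D1:**
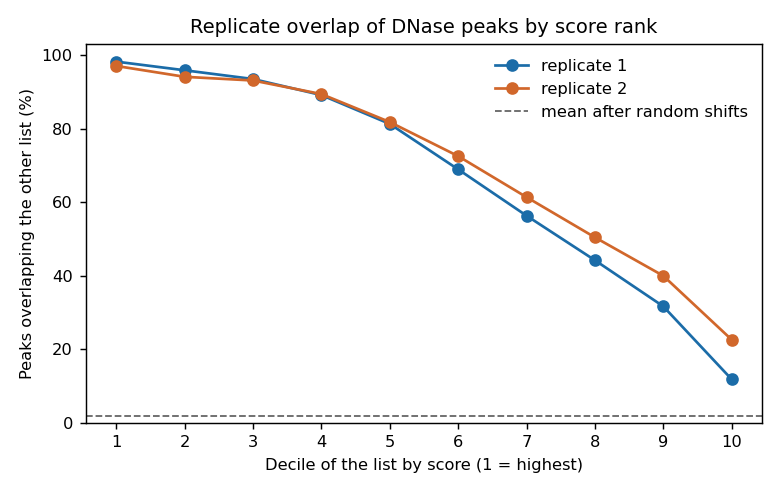
Share of peaks (%) that overlap a peak of the other library, by decile of the list ranked by score, for replicate 1 and replicate 2, with the mean after random shifts as a dashed line. The share falls from 98.2% and 97.03% in the highest decile to 11.8% and 22.6% in the lowest.

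Promoters held 23.7% of the peaks of replicate 1 and 24.5% of those of replicate 2, against 3.77% and 3.81% of shifted peaks. Exons held 3.799% and 4.112%, introns 34.3% and 35.3%, and intergenic sequence 38.2% and 36.0%, where shifted peaks gave 59.3% in both libraries. The loci with most shared peaks had 64 within 50 kb of the start of Cbarp, a calcium channel regulator, 61 round Vamp2, which encodes the synaptic vesicle protein synaptobrevin, and 53 round Rara, the retinoic acid receptor alpha. Gm49450 had 58 and Cfd, complement factor D, had 52. The other loci among the 15 densest were Kdm6b, a histone demethylase, Cic, Hook2, Icmt, Btn2a2, Bahcc1, Fgr, Adam15, Dhx16 and Dohh, with 47 to 51 shared peaks each. The median over all protein-coding genes was 8. Cfd and Fgr, a kinase of myeloid cells, were the members of these 15 without a promoter peak of their own in either library. The windows of these 15 held 1 to 10 protein-coding start sites, so their density is not matched for gene number.

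Of 21911 protein-coding genes, 12914 (58.9%) had a promoter peak in both libraries, 406 in replicate 1 only, 368 in replicate 2 only and 8223 in neither. The share rose with promoter CpG content, from 5.75% in the lowest decile to 90.6% in the highest, and the gene lists were therefore matched on it.

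Genes of neuronal structure and secretion had promoter peaks almost throughout. In the pan-neuronal list 23 of 24 members had one in both libraries, among them Tubb3, the neuronal beta-tubulin (chromosome 8, 123411424 to 123422015), Nefh, the heavy neurofilament, Syt1, the calcium sensor of synaptic vesicle release, and Map2, a dendritic microtubule protein. The best promoter peak of Tubb3 was at the 99.7 percentile of score in replicate 1 and the 99.9 percentile in replicate 2. The exception was Dcx, a microtubule protein of young neurons, which had no peak in either. Matched random lists gave a mean of 17.8 (middle 95%: 14 to 21; permutation p = 0.0102, adjusted p = 0.0374). With replicate 2 alone the adjusted permutation p was 0.0519, and with a promoter window of 2.5 kb it was 0.0671, so the list no longer passed.

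Markers of single neuronal types were present in part. The motor neuron list had 12 of 20 promoters with a peak in both libraries, including the LIM factor Isl1, Lmo4, Prph, which encodes peripherin, and Ache, which encodes acetylcholinesterase. Mnx1, Olig2 and Nkx6-1, transcription factors of the motor neuron lineage, and Slc5a7, the choline transporter, had none. The other members were named after their values were seen. Isl2, Lhx3, Lhx4, Chat, Slc18a3, Neurog2, Foxp1 and Ret had peaks in both libraries, and Onecut1, Aldh1a2, Pou3f1 and Chodl had none. The list did not pass (mean of matched lists 14.8, adjusted permutation p = 0.209). The sympathoadrenal list also had 12 of 20 (mean 15.1, adjusted permutation p = 0.194). Its members with peaks included Gata2 (chromosome 6, 88193891 to 88207032), Slc18a1, a vesicular monoamine transporter, Alk and Mycn, while Hand1, Th and Ddc, the last 2 being enzymes of catecholamine synthesis, and Sox11 had none. Dbh, named after its value was seen, had a promoter peak in replicate 2 only. With a promoter window of 2.5 kb Th, Ddc and Dbh each had a peak in both libraries. So did Sox10, Myog, Kdr, Cd3e and Spi1, named below in lists of other cell types, so this was not particular to sympathoadrenal genes. The ratio of the sympathoadrenal list to matched lists was 1.02 with that window. The list lay below its matched level with 1 start site per gene (adjusted permutation p = 0.0386) and with the higher-scoring peaks of each list (0.0436).

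The neural progenitor and monoaminergic other lists lay below their matched level, and 3 further lists did not pass. The neural progenitor list had promoter peaks at 8 of 15 genes, where matched lists gave a mean of 12.6 (permutation p = 0.00580, adjusted p = 0.0255). Pax6, Vim, Hes5 and Prom1 had peaks, and Sox1, Sox2, Sox3 and Pou3f2, transcription factors of neural progenitors, had none in either library. The monoaminergic other list had 5 of 11 against a mean of 8.81 (adjusted permutation p = 0.0415), with peaks at Nr4a2, Tph2, Pitx3 and Fev and none at Slc18a2, Slc6a3, Lmx1a and En1. With replicate 2 alone the adjusted permutation p was 0.0760 for neural progenitor genes and 0.122 for the monoaminergic list, and without CpG matching it was 0.937 and 0.6998. The glutamatergic list had 4 of 12 (mean 7.73, adjusted permutation p = 0.0818), with peaks at the receptor genes Grin1 and Gria2 and at Slc17a7, a vesicular glutamate transporter, and none in either library at 7 members. The GABAergic and glycinergic list had 5 of 12 (mean 8.69, adjusted permutation p = 0.0650), with peaks at Dlx1 and Dlx2 and none in either library at 6 members. The glia and neural crest list had 8 of 18 (mean 10.7, adjusted permutation p = 0.220), with a peak at Erbb3 and none at Sox10 and Foxd3. Of the genes named here, Pax6, Pitx3 and Dlx1 had no promoter peak in both libraries when 1 start site per gene was used. Sox3 had a promoter hotspot in replicate 2 only.

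Outside the nervous system, the housekeeping list passed above its matched level, and the germ line, pluripotency, epithelial and skeletal muscle lists passed below it. All 20 housekeeping genes had promoter peaks in both libraries, Actb and Ppia among them (mean of matched lists 15.8, adjusted permutation p = 0.0255). All 21 cell cycle genes had them too, including E2f1, Ccna2, Ccnb1 and Cdk2. The matched mean was 17.7 and the adjusted permutation p was 0.0902, but a full list is the ceiling, so no higher count was possible. None of 12 germ line genes had a promoter peak, including Ddx4, Dazl, Sycp1 and Sycp3, against a mean of 7.30 (adjusted permutation p = 0.00440). The raw p of this list, 0.0002, is the smallest the random lists can give. The pluripotency list had 4 of 16 against 10.1 (adjusted permutation p = 0.0220), with peaks at Klf2, Klf4, Lin28a and Pou5f1 and none at Nanog, Esrrb, Zfp42 and Dppa4. The epithelial list had 4 of 15 against 9.35 (adjusted permutation p = 0.0249, and 0.0568 without CpG matching). It had peaks at Elf3 and Krt8 and none at Epcam and Cdh1, which encodes E-cadherin. The skeletal muscle list had 4 of 16 against 8.49 (adjusted permutation p = 0.0434), with a peak at Pax3 and none at the muscle-determining factors Myod1, Myf5, Myf6 and Myog.

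Altogether 8 of the 22 lists passed the threshold at promoters, 2 above and 6 below their matched level. More lists passed with 1 start site per gene and in the higher-scoring part of each list, as given below. In the main setting peaks at any start site were counted, but CpG content was matched at the outermost start site only. Whether this limit of the matching changed which lists passed was not tested. With replicate 2 alone 3 passed, the germ line, pluripotency and epithelial lists. The adjusted permutation p of the housekeeping list was then 0.0517 and that of the skeletal muscle list 0.118, which was 0.122 with replicate 1 alone. With a 2.5 kb window 2 lists passed, pluripotency and epithelial, and the germ line list had an adjusted permutation p of 0.0671. Other lists that did not pass were erythroid and megakaryocyte (8 of 15 genes, adjusted permutation p = 0.246), cardiac (6 of 12, 1), mesenchymal and fibroblast (6 of 17, 0.0981), endothelial (5 of 14, 0.203), hepatocyte (4 of 15, 0.214), T cell (3 of 13, 0.194), B cell (3 of 12, 0.420) and myeloid (2 of 15, 0.0820). Peaks stood at the promoters of Tal1 and Itga2b but not Gata1 among the erythroid and megakaryocyte genes, at Gata4 and Nkx2-5 but not Tbx5 among the cardiac genes, at Fn1 and Col1a1 but not Twist1 among the mesenchymal genes, and at Egfl7 but not Kdr among the endothelial genes. They stood at Foxa1 but not Alb among the hepatocyte genes and at Lck but not Cd3e among the T cell genes. Pax5 among the B cell genes and Cd68 but not Spi1 among the myeloid genes had them too. With 1 start site per gene Itga2b, Egfl7, Lck and Pax5 had no such peak in both libraries, and Cd3e had a promoter hotspot in both.

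**Figure D2:**
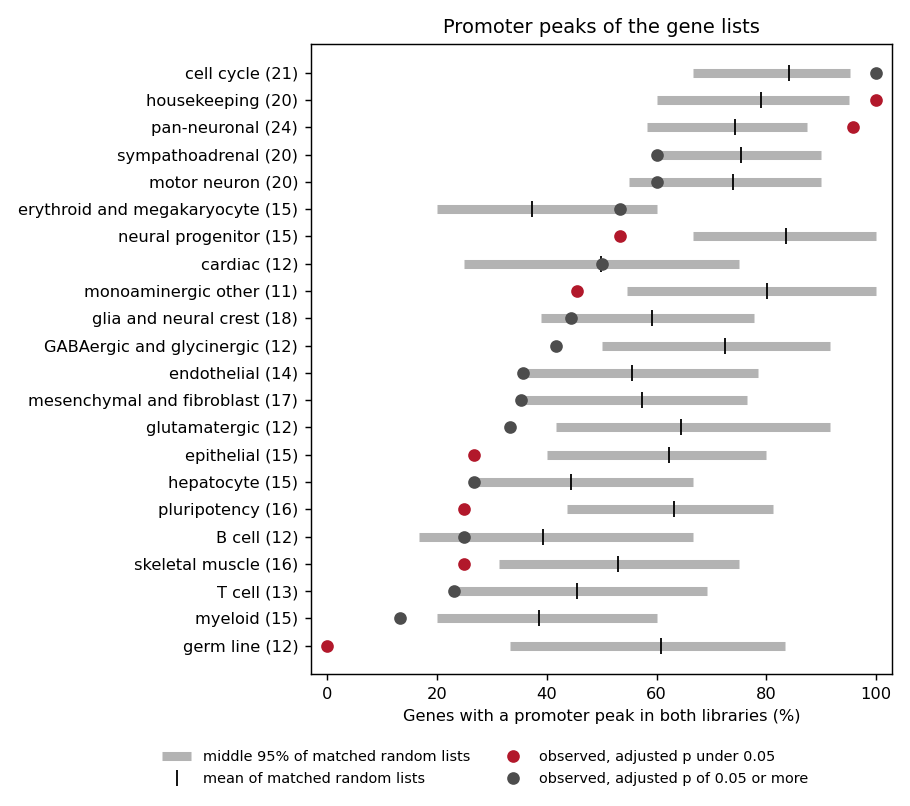
Share of genes (%) with a promoter peak in both libraries for each of the 22 gene lists (points; number of genes in brackets), with the mean (tick) and middle 95% (grey bar) of 10000 random lists matched on CpG content. Red points have an adjusted permutation p under 0.05, among them pan-neuronal genes at 95.8% and germ line genes at 0%.

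Among the 22 gene lists, the ratio of shared distal peaks to matched lists was highest for the sympathoadrenal genes. They had a mean of 10.6 shared distal peaks within 50 kb, 2.24 times the 4.74 of random lists matched on gene density, and all 20 members had at least 1. Gata2, a transcription factor of sympathetic neurons and blood cells, had 26. Hand1 had 17 and Ddc 14 without a promoter peak of their own, while Alk had 4 and Th 5. The permutation p was 0.0002, the smallest the random lists can give (adjusted p = 0.00220), and the adjusted p stayed at or below 0.0176 in 8 of 8 alternatives.

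Pan-neuronal genes had a mean of 9.79 shared distal peaks, 1.94 times the matched 5.04 (permutation p = 0.0002, adjusted p = 0.00220). Tubb3 had 28 and Nefh 21, Syt1 and Map2 had 3 each, and Dcx had none. Within 100 kb the ratio was 1.52 and the adjusted permutation p 0.129. Housekeeping genes had a mean of 10.2, 1.78 times the matched level (adjusted permutation p = 0.0161), with 25 at Actb and 16 at Snrpd3. With replicate 1 alone their ratio was 1.60 (adjusted permutation p = 0.125), and with the higher-scoring peaks of each list it was 1.86 (0.0836). The other 19 lists did not pass, with ratios from 0.702 for glutamatergic to 1.55 for skeletal muscle genes and adjusted permutation p of 0.256 or more. Motor neuron genes had a ratio of 1.41 (adjusted permutation p = 0.362). Members whose windows overlap count the same peak more than once.

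Hox genes, whose clusters record position along the body axis, were split by cluster. Promoter peaks in both libraries were found at 6 of 11 genes of the A cluster (among them Hoxa4, Hoxa5, Hoxa6, Hoxa7 and Hoxa10) and at 5 of 9 of the C cluster (Hoxc4, Hoxc5, Hoxc6, Hoxc9 and Hoxc10). None of the 10 genes of the B cluster and none of the 9 of the D cluster had one. In the A and C clusters, no gene with a paralog number of 11 or more had a promoter peak in either library, though Hoxc11 had one in both with a window of 2.5 kb. Hoxa3 and Hoxb6 had one in replicate 2 only and Hoxb13 in replicate 1 only. Between the outermost genes there were 34 shared peaks in the C cluster (chromosome 15, 102921103 to 103036852), 14 in A (chromosome 6), 6 in B (chromosome 11) and 5 in D (chromosome 2). With a promoter window of 2.5 kb the counts were 7 in A, 1 in B, 6 in C and 2 in D. With 500 bp they were 6 in A, 0 in B, 4 in C and 0 in D, and Hoxc4 had none. The annotated spans of Hoxc5 and Hoxc10 begin at 102967443 and 102966796, so 1 peak may count for both genes. No test was run on the clusters.

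Binding sequences of several factor classes were more frequent in shared peaks than in flanking sequence. Among the 83239 shared distal peaks, 5.55% held a match to the motif of CTCF, a protein of chromatin loop anchors and insulators, 34.1 times the share in flanking sequence. The AP-1 motif, bound by Fos and Jun proteins, was in 12.1% of them, 4.51 times the flanks. The paired homeodomain motif of PHOX2 factors, regulators of autonomic neurons, was 4 times as frequent as in flanks, but in 0.276% of the peaks. Motifs of NFI (23.9), RFX (13.4), which regulates cilia genes, CRE (3.99) and the E-box CAGCTG (2.07), bound by basic helix-loop-helix factors, were also over 2 times the flanks, with NFI in 0.244%, RFX in 0.185% and CRE in 0.511% of the peaks. At the 30983 shared promoter peaks the ratio was highest for CTCF (9.49), followed by NRF1 (7.77), ETS (7.34), CRE (6.66) and RFX (6.46). It was 4.38 for SP/KLF and 3.34 for NFY.

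Of 32 motifs, 12 exceeded all their shuffles at distal peaks: the 7 above and SP/KLF (1.56), MEF2 (1.45), GATA (1.35), homeodomain TAATTA (1.27) and IRF, whose ratio was 0.872. At promoter peaks 16 did, 7 of them with a ratio under 1 (homeodomain TAATTA, IRF, FOX, MEF2, PHOX2, CEBP and OCT), and NRF1 did not, since 1 of its shuffles had a ratio of 18. The ETS ratio at distal peaks, 2.15, was below its highest shuffle, 2.53. SOX (0.956), OCT (0.927), RUNX (0.992) and HNF4 (1.02) were near the flanks, and HSF was at 0.532. Using every peak of replicate 2, the distal ratio of the PHOX2 motif was 2.46, against 3.46 with those of replicate 1. At promoter peaks the RFX ratio was 3.39 and 5.41. A consensus match does not show that a factor was bound.

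**Figure D3:**
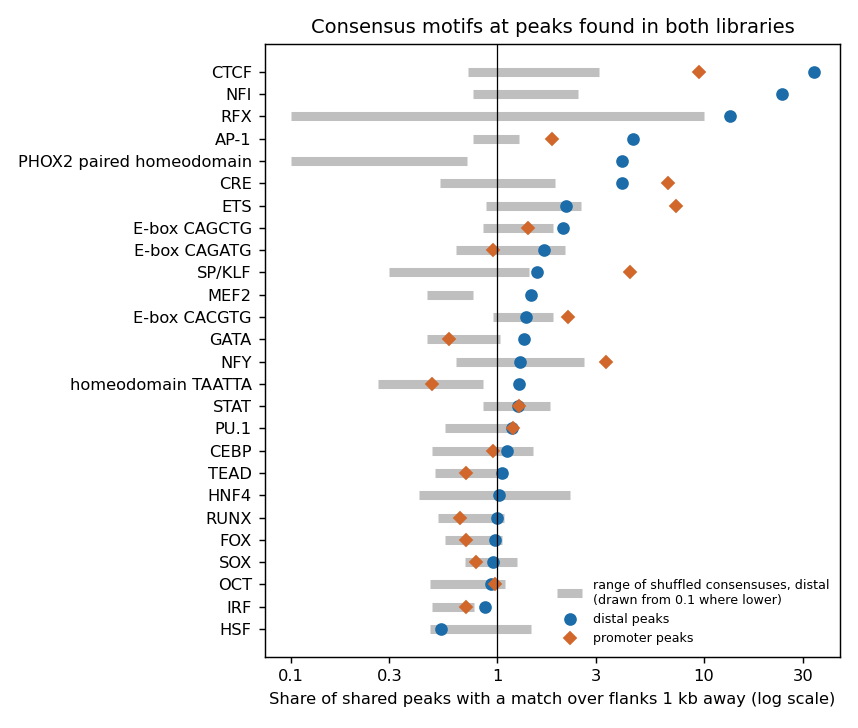
Share of shared peaks with a consensus motif divided by the share in flanks 1 kb away (log scale), at distal (circles) and promoter peaks (diamonds), with the range of shuffled consensuses at distal peaks in grey, for motifs with at least 100 matches. CTCF stands at 34.1 and NFI at 23.9 at distal peaks.

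The libraries differed most at loci where replicate 1 had many peaks that replicate 2 lacked. Within 50 kb of Apol7e on chromosome 15 it had 112 peaks and replicate 2 had 10, at Gpr33 on chromosome 12 the numbers were 91 and 6, and at Acyp2 on chromosome 11 they were 90 and 7. Ly6g (82 and 2), Fam129a (81 and 11), Macf1 (85 and 16), Mterf1b (77 and 8), Zfp992 (69 and 1), G6pd2 (68 and 1) and Rrp15 (77 and 16) followed. None of these 10 genes belongs to a gene list, and 9 of the 10, with G6pd2 as the exception, had a dense block of peaks found in replicate 1 only within the window. By the block rule, chosen after these loci were seen, replicate 1 had 45 blocks on 11 chromosomes. They covered 2100 kb and held 2730 peaks, 1.60% of its list, with a median score of 11 against a 5th percentile of 18 for the list. Replicate 2 had 2 blocks with 98 peaks. No test between 1 library and 1 other is possible.

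By chromosome, replicate 1 had a larger share of its peaks on X (2.15% against 1.89%, ratio 1.14) and on chromosome 1 (ratio 1.08), and a smaller share on chromosomes 6 (0.927) and 19 (0.932). Chromosome 16 had a ratio of 1.06. On Y there were 69 and 43 peaks. Among the 19 autosomes 4 differed by more than 5%, and with lists of equal length 1 did, chromosome 19 (0.948), with X at 1.09. With the blocks left out, the ratio was 1.05 for chromosome 1 and 1.16 for X.

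In the distal peaks found in 1 library only, the libraries differed in motif content. A CTCF match was in 1.73% of the 44091 such peaks of replicate 1 and 0.287% of the 39439 of replicate 2, a ratio of 6.05 (95% bootstrap interval 4.98 to 7.50). The NFI motif went the other way, with 0.109% and 0.411% (ratio 0.265, 0.185 to 0.360), as did AP-1, with 6.58% and 9.51% (ratio 0.692, 0.661 to 0.725), and RFX (0.530, 0.335 to 0.793). SP/KLF had a ratio of 0.386 (0.313 to 0.473), and at equal GC content 0.752 (0.606 to 0.912). The PHOX2 motif had a ratio of 2.78 (1.96 to 4.17), which was 1.52 (1.05 to 2.28) at equal GC content. Homeodomain TAATTA had 1.60, and at equal GC content 1.03 (0.965 to 1.10). Among all distal peaks, shared or not, a CTCF match was in 4.15% of the 129897 of replicate 1 and 3.89% of the 122804 of replicate 2. Of the distal peaks with a CTCF match, 85.8% of the 5390 of replicate 1 were shared and 97.6% of the 4783 of replicate 2. Peaks in blocks were left out of the single-library sets, and the intervals cover the sampling of peaks within these 2 libraries, not differences between cultures.

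**Figure D4:**
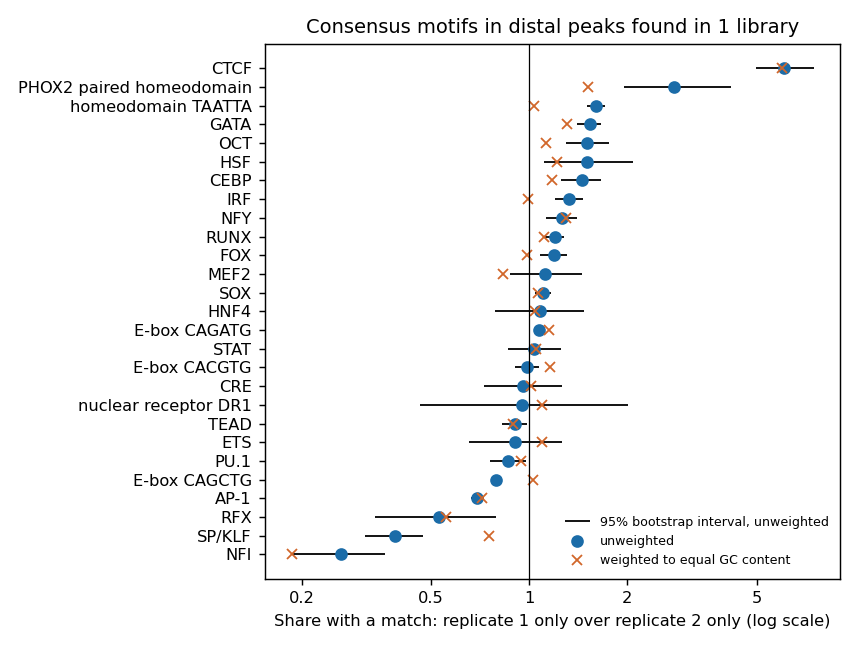
Share of distal peaks with a consensus motif in replicate 1 only divided by that in replicate 2 only (log scale), with 95% bootstrap intervals (lines) and the ratio at equal GC content (crosses). CTCF stands at 6.05 and NFI at 0.265.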

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

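In this part, 1 test, that of block numbers at equal list length, was chosen after its result was seen. The other tests were written down before their values were known but after the patterns themselves had been seen.

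Peaks outside the main chromosomes were not used in any comparison. Replicate 2 had 17 peaks on the mitochondrial chromosome, with a median score of 150 (range 124 to 150), between positions 1416 and 16225, where replicate 1 listed 0. On unplaced and unlocalized scaffolds replicate 1 had 314 peaks and replicate 2 had 275. The counts of 17, 314 and 275 were flagged only because each exceeded 3 peaks, and no expected number was compared.

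A CTCF match was in 4.15% of all distal peaks of replicate 1 and 3.89% of those of replicate 2. CTCF matches were more frequent in the distal peaks of replicate 1 only than in those of replicate 2 only. The difference was not explained by GC content, since the ratio was 5.98 (95% bootstrap interval 4.73 to 7.54) at equal GC content. Whether score rank within the list plays a part was not decided. At equal score deciles the ratio was 6.24 (5.15 to 7.89), with its interval above the bound of 2 set against it beforehand. That weighting moved the other motifs little, by a median of 1.40%, so it was too small a change to decide the question. Equal rank need not be equal signal, since the score has no stated normalization. A weaker signal at CTCF sites throughout replicate 2 may remain. At shared distal peaks the score percentile of replicate 1 exceeded that of replicate 2 by 1.18 points more (1.06 to 1.51) with a CTCF match than without. The difference lay under the bound of 2 points set against this explanation, but sites lost from replicate 2 could not enter this test. No biological explanation was tested, since the series holds 1 group, and a difference in library preparation or sequencing cannot be separated from the replicate.

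Hoxb and Hoxd promoters lacked shared peaks while Hoxa and Hoxc promoters had them. Loss of the sequence of either whole cluster is argued against by shared peaks within both, at least 5 in each. The calling threshold of the peak lists may account for the pattern and stays open: hotspots lay at 10.5% of the Hoxb and Hoxd promoters (2 of 19) in either library, under the bound set against it, but they matched the peak calls at all Hox promoters and so added no looser call. Loss of single promoters was not tested, nor was any biological explanation.

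Blocks of dense weak peaks were found in replicate 1 and seldom in replicate 2. Their median soft-masked share was 43.9%, above that of random segments of the same lengths (median 31.1%, 26.9% to 35.8%). Repeated sequence that maps ambiguously therefore stays a candidate explanation for part of the pattern. The random segments were not matched on location, and 79.8% of the block peaks of replicate 1 were intergenic. Ambiguous mapping itself was not measured. The sequence is the same for both libraries, so the test cannot say why the blocks appeared in replicate 1. A copy number gain of the segments between neighbouring blocks stays open. Of these intervals, 42.9% (3 of 7) had a score shift above the 95th percentile of random intervals. That share met the bound set beforehand for this explanation, but 7 intervals are too few to decide. A gain of the blocks themselves was not tested. Whether a longer list of weak peaks in replicate 1 plays a part was not decided: with lists of equal length replicate 1 had 4 blocks and replicate 2 had 2 (50%), but that limit removes the lowest-scoring peaks, which make up the blocks, so its outcome was fixed. No biological explanation was tested.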

How the results depend on the processing

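The alternatives without blocks and without peaks of decimal score were chosen after seeing the data, and the others were planned. The cause of the changes below was not tested, except that a wider window, a stricter overlap or fewer peaks changes a share by construction. At promoters the pluripotency list passed in 10 of 10 alternatives (adjusted p up to 0.0434), the epithelial and germ line lists in 9, the housekeeping and pan-neuronal lists in 8, the neural progenitor and monoaminergic other lists in 7 and the skeletal muscle list in 5. The skeletal muscle list lost its call in the higher-scoring part of each list (adjusted p 0.0820), among others. At distal peaks the sympathoadrenal list passed in 8 of 8, the pan-neuronal list in 7 and the housekeeping list in 6. Hox promoters with a shared peak numbered 10 to 16 in the alternatives, against 11. Distal motifs with a ratio above 2 numbered 7 to 11, against 8.

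Mean overlap of the libraries was 68.6%, and 63.0% when 50% of both peaks had to overlap and 80.8% in the higher-scoring part of each list. The highest decile had 97.6%, and 94.4% with 50% overlap. Peaks with 50% of their length in a hotspot made up 95.2%. The mean promoter share was 24.1%, and 16.4% with a 500 bp window, 33.8% with 2.5 kb and 34.1% in the higher-scoring part. Autosomes more than 5% apart fell from 4 to 1 with lists of equal length. Genes with a promoter peak in both libraries were 57.2% (500 bp), 62.7% (2.5 kb), 54.5% (1 start site per gene), 55.7% (higher-scoring part), 59.4% (hotspots) and 60.6% to 60.8% when 1 replicate was left out. Promoter lists past the threshold numbered 2 (2.5 kb), 15 (1 start site per gene), 13 (higher-scoring part) and 3 to 7 when 1 replicate was left out.

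Lists that did not pass at promoters but did in some alternatives were cell cycle, GABAergic and glycinergic, endothelial and myeloid (3 each), sympathoadrenal (2), and mesenchymal and fibroblast, T cell and hepatocyte (1 each). Cell cycle genes were then above and the others below their matched level.

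Of the lists whose direction reversed, none had passed. At promoters the ratio to matched lists became 1.02 for sympathoadrenal genes (2.5 kb and without matching), 1.02 for motor neuron genes and 0.903 for erythroid genes (without matching). For cardiac genes it became 0.906 (2.5 kb), 0.990 (hotspots), 0.849 (without matching) and 0.954 to 0.959 when 1 replicate was left out. At distal peaks it became 0.957 for germ line genes (20 kb), 0.930 (100 kb) and 1.00 (without matching) for neural progenitor genes, and 1.01 for endothelial genes (100 kb). In the higher-scoring part it became 0.727 for erythroid, 0.863 for T cell and 1.01 for hepatocyte genes, which also had 1.01 without decimal scores. When 1 replicate was left out it was 0.955 to 0.969 for erythroid, 0.977 to 1.01 for T cell, 0.953 to 1.06 for epithelial and 0.969 to 1.01 for pluripotency genes. What read depth limits cannot be stated, since depth is unknown.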

Other observations

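All tests in this part were chosen after seeing the gene results. They compared 33 gene families with 10000 random lists matched in the same way, adjusted over the families, at the main setting only.

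Of the 33 families, 13 passed the threshold with fewer promoter peaks than matched genes and 3 with more. Those that did not pass lay on both sides, most of them below. Of the channel families named here, potassium channels passed, while sodium channel genes (7 of 10, matched mean 5.49, adjusted permutation p = 0.596) and voltage-gated calcium channel genes (17 of 26, mean 16.5, 1) did not. Nicotinic acetylcholine receptor genes (5 of 16, mean 6.97, 0.513) and the LIM homeobox, POU, GATA, T-box and Dlx factor families did not pass either. Families were set by gene symbol. Of 19 genes with symbols of ionotropic glutamate receptors, 5 had a promoter peak in both libraries, against a matched mean of 13.9. They were Grin1, Gria2, Grik5, Grin2d and Grid2ip, the last not itself a receptor subunit. Of 19 GABA-A receptor genes, 2 had such a peak (mean 10.3), and of 93 potassium channel genes, 37 did (mean 60.03). Among transcription factors, NKX genes had 1 of 14 (Nkx2-5; mean 11.2), Irx genes 1 of 6 (Irx5; mean 5.25), PAX genes 3 of 9 (Pax3, Pax5 and Pax6; mean 6.32), SOX genes 7 of 19 (mean 15.99) and forkhead genes 22 of 44 (mean 34.7). Cadherins with a Cdh symbol had 6 of 23, keratins 3 of 49 and collagens 18 of 44. Olfactory receptors had 19 of 1134 and vomeronasal receptors 2 of 330. The largest adjusted permutation p among these families was 0.0379, that of collagens. Ribosomal proteins (74 of 76), proteasome subunits (37 of 39) and Zfp zinc finger genes (304 of 365) were above their matched means.

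Shared distal peaks were concentrated round Wnt ligands, the secreted signals of development, with a mean of 12.6 within 50 kb, 2.51 times the matched level. Clustered histone genes had 1.74 times, ephrins and Eph receptors, which guide axons, 1.72 times, voltage-gated calcium channel genes 1.62 times and ribosomal proteins 1.42 times the matched level. The largest adjusted permutation p among these 5 families was 0.0324. The 6 families that passed below their matched level included vomeronasal receptors (0.0577 times) and olfactory receptors (0.109 times). GABA-A receptor genes had 0.192 times, keratins 0.343 times, cytochromes P450 0.480 times and Zfp zinc finger genes 0.762 times the matched level. Genes of 1 family often lie side by side and share peaks, which the random lists do not mimic. Among genes of the SOX, forkhead, LIM homeobox, POU, GATA, T-box, Dlx, Irx, PAX and NKX families, Sox8 had most shared distal peaks (32). It was followed by Gata2 (26), Foxk1 (22), Foxl1 (20) and Gata5 (19).

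In the peak lists, 13086 peaks of replicate 1 and 9864 of replicate 2 had a score with a decimal, with medians of 29 and 20 against 52 and 41 for the other peaks.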
